A study of Homo sapiens with 20 samples.

How the data were processed

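HEL cells were cultured in RPMI and treated in duplicate with DMSO, BCI, BI-D1870 or both inhibitors, and JAK2 inhibitor persistent cells were made by prolonged culture with the inhibitor, per the labels' protocols. Total RNA was extracted with RNeasy columns and DNase and sequenced on a NovaSeq, per the labels. Per the submitters' processing notes, reads were demultiplexed with bcl2fastq and aligned with STAR 2.5.1a to GRCh38, and edgeR was used. Deposited values are raw counts per gene, in 3 tables, per the labels. The annotation release, the counting program, its strand setting and the library kit are not given in the sources used here, so reads of genes that overlap on opposite strands may be shared. Even values made up 59.8 to 73.1% of counts from 1 to 20, so both mates of a read pair were probably counted and a fragment may stand for 2 counts.

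Each of the 20 libraries was assigned to 1 of 10 groups of 2 from the labels and column headings, and no value column was left without a sample. The later columns of the BCI table are headed 24h, while the labels give 48 h for them, and the labels were followed. Columns of the BI-D1870 table give no time, and the labels give 24 h. The tables held 55209, 55209 and 34343 lines, of which 116, 116 and 130 repeated a gene with a further Entrez identifier and the same counts, and 1 of each was kept. Symbols and identifiers are those of the tables, and positions are from GENCODE 29. Tables were fitted and tested separately, since each holds its own controls and the persistent table lists fewer genes.

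CPM are counts scaled by TMM library size. Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were filtered with filterByExpr by group, scaled with TMM and fitted with all groups of a table in 1 quasi-likelihood model without a replicate block. Genes were called at Benjamini-Hochberg adjusted p under 0.05. Standard errors are the log2 fold change over the root of the test statistic. The floor of 3 counts is the upper limit that a count of 0 allows, by counting alone, and is 2 times as high if a fragment stands for 2 counts. The 9 comparisons were BCI against DMSO at 4 h and 48 h, the difference of these, BI-D1870 and the pair each against DMSO, the pair against BI-D1870, RuxP and FedP each against parental, and FedP against RuxP. Residual degrees of freedom were 4, 3 and 3.

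The 30 lists written before the files were opened were tested with camera of limma 3.58.1, two-sided, with a preset correlation of 0.01 and at least 5 members tested. They were ERK feedback and immediate-early genes, MAP kinase phosphatases, RSK and MSK kinases, JAK, STAT and cytokine receptor genes, STAT5 target genes, interferon-stimulated genes, antigen presentation genes, NF-kappaB and TNF response genes, S100 genes, erythroid genes, megakaryocyte and platelet genes, monocyte and granulocyte genes, haematopoietic stem and progenitor genes, DNA replication genes, mitosis genes, ribosome biogenesis genes, ribosomal protein genes, cholesterol synthesis genes, ATF4 response genes, endoplasmic reticulum stress genes, heat shock genes, NRF2 target genes, p53 target genes, BCL2 family genes, hypoxia and glycolysis genes, drug efflux transporter genes, mitochondrially encoded genes, replication-dependent histone genes, lymphoid marker genes and epithelial and stromal marker genes. Carried sets, of genes called in another table, were tested in the same way. Genes named in the text follow a rule set before the files were opened. It names 11 focus genes in every comparison. It adds the 10 genes with the largest rises and the 10 with the largest falls, or 5 for the 48 h against 4 h and FedP against RuxP comparisons. These pass the threshold, have a mean of at least 4 CPM and, outside the 48 h against 4 h comparison, have both libraries of 1 group above both of the other. It also adds up to 4 passing members of each list described. The text names a part of these. XIST, Y-linked genes, pseudogenes and unnamed transcripts were left out of the names.

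The code was tested on simulated data with 200 changed genes. At 1.5, 2 and 4-fold it recovered 40.3%, 85.1% and 98.5% for BCI at 4 h and 43.3%, 85.1% and 100% at 48 h. It recovered 83.6%, 95.5% and 100% for BI-D1870, 79.1%, 92.5% and 98.5% for the pair and 85.1%, 94.0% and 100% for BCI on top. For RuxP it recovered 4.48%, 10.4% and 78.8%, for FedP 0%, 13.4% and 92.4% and for FedP against RuxP 0%, 14.9% and 80.3%. The difference between the times was not simulated. Correlations between comparisons with a shared control were set beside 20 simulated tables without any change.

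Alternatives were DESeq2 size factors, no or a stricter low-count filter (at least 1 CPM in every group mean or 10 in any library), DESeq2 1.42.0, limma-voom, only the groups compared, a replicate block, each library left out, a fold change of at least 1.5, an estimated correlation, sets of at least 2-fold changed genes, and genes with a mean of at least 4 CPM. Halved counts, removal of GC and transcript length trends by a smooth curve per library, and leaving out the 2 least complex persistent libraries together were added after the data were seen. Sequence variants and splicing need reads and were not analysed here.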

Results

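RNA of HEL cells, a human erythroleukaemia line, was sequenced in 20 libraries of 10 groups of 2, and the deposited gene counts came in 3 tables. The first table held cells given 1 µM BCI, an inhibitor of the phosphatases DUSP1 and DUSP6, or the solvent DMSO, for 4 h or 48 h. The second held cells given DMSO, 10 µM BI-D1870, an inhibitor of RSK kinases, or BI-D1870 with BCI, for 24 h per the labels. The third held parental cells and cells kept in long culture with a JAK2 inhibitor, named here RuxP (ruxolitinib-persistent) and FedP (fedratinib-persistent). Libraries held 63916850 to 84452743 counts in the first table, 54141164 to 70128404 in the second and 51799814 to 79755715 in the third. Column headings of the first table gave 24 h where the labels gave 48 h, and the labels were followed. After filtering, 21908, 21328 and 15924 genes were tested. The biological coefficient of variation was 13.3%, 5.01% and 26.9%. The records say that drug-treated cells were treated in duplicate, and no source used here says whether replicates were independent experiments, so p-values measure only the spread between these samples, and the tables were tested separately.

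Genes followed through every comparison were the ERK phosphatases DUSP6 (ENSG00000139318, chr12:89347232-89353271) and DUSP1 (ENSG00000120129, chr5:172768090-172771195), the RSK kinase RPS6KA1 (ENSG00000117676, chr1:26529761-26575030), the kinase JAK2 (ENSG00000096968, chr9:4984390-5128183), the ERK-induced EGR1 (ENSG00000120738, chr5:138465490-138469315) and the ERK inhibitor SPRY4 (ENSG00000187678, chr5:142310427-142326455). Further ones were the STAT5 targets PIM1 (ENSG00000137193, chr6:37170203-37175426) and CISH (ENSG00000114737, chr3:50606490-50611831), the growth regulator MYC (ENSG00000136997, chr8:127735434-127741434), and the myeloid alarmins S100A8 (ENSG00000143546, chr1:153390032-153391188) and S100A9 (ENSG00000163220, chr1:153357854-153361027). Positions are those of GENCODE 29 on GRCh38. S100A8, S100A9 and SPRY4 had too few counts to be tested in any table. S100A8 had 0 to 3 counts per library. S100A9 had 0 to 2 in the BCI and BI-D1870 tables and at most 46, in 1 RuxP library. SPRY4 had 0 to 22. The level of 3 counts ran from 0.0355 to 0.0579 CPM, a floor that covers counting error only and doubles if a fragment stands for 2 counts.

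The first question was what BCI does to HEL cells at 4 h. Target activity was not measured for either compound. Of 21908 genes, 1052 rose and 1302 fell under BCI (edgeR, adjusted p under 0.05), with 270 up and 148 down at least 2-fold. Values marked log2 are log2 fold changes, and CPM are counts scaled by library size. Stress genes made the largest rises. HMOX1 (ENSG00000100292), the haem-degrading enzyme of the oxidative stress response, rose to 1274 ± 117 CPM against 9.64 ± 0.517 (mean ± SD, n = 2; log2 7.05, SE 0.208, adjusted p = 6.9e-07). OSGIN1, an oxidative stress growth inhibitor, rose with it (log2 5.72, SE 0.485, adjusted p = 2.0e-04). The co-chaperones BAG3 (346 ± 50.7 against 26.3 ± 0.816; log2 3.72, SE 0.202, adjusted p = 1.4e-05) and DNAJB1 (1682 ± 234 against 175 ± 0.0862; log2 3.26, SE 0.125, adjusted p = 1.6e-06) rose too. HSPA1A and HSPA1B, log2 fold changes 4.40 (SE 0.470, adjusted p = 6.0e-04) and 4.39 (SE 0.334, adjusted p = 1.1e-04), are near-identical copies, so the split of reads between them is uncertain. The largest fall was that of TRIM67, a ubiquitin ligase gene (2.30 ± 0.172 against 16.6 ± 1.66; log2 -2.85, SE 0.209, adjusted p = 9.3e-05). Falls of the cyclin CCND1 (4.52 ± 0.782 against 14.5 ± 0.243; log2 -1.68, SE 0.162, adjusted p = 3.5e-04) and the receptor KIT (9.68 ± 0.126 against 29.4 ± 1.90; log2 -1.60, SE 0.220, adjusted p = 0.0020) followed.

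Among the genes followed, the targets of the compound moved in opposite directions at 4 h. DUSP6 fell (13.7 ± 0.508 CPM against 27.4 ± 0.863; log2 -1.003, SE 0.0999, adjusted p = 4.1e-04) and DUSP1 rose (21.2 ± 3.98 against 8.36 ± 0.263; log2 1.34, SE 0.163, adjusted p = 0.0012). RPS6KA1 fell (log2 -0.64, SE 0.0778, adjusted p = 0.0012), as did PIM1 (426 ± 10.3 against 704 ± 0.146; log2 -0.72, SE 0.137, adjusted p = 0.0099), CISH (log2 -0.47, SE 0.0989, adjusted p = 0.017) and MYC (605 ± 3.15 against 896 ± 6.77; log2 -0.57, SE 0.145, adjusted p = 0.037). JAK2 (0.27, adjusted p = 0.11) and EGR1 (0.56, adjusted p = 0.12) did not pass. With any 1 library left out PIM1, CISH and MYC did not pass (highest adjusted p = 0.11, 0.20 and 0.22), nor did MYC with GC and length trends removed (adjusted p = 0.075).

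Heat shock genes took up the response most fully. In that list 17 rose, 0 fell and 1 did not pass (18 and 0 adjusted over the list alone, median 1.59, adjusted p = 9.7e-108, adjusted p = 0.0081 with an estimated correlation), with HSPH1 at 2.54, HSP90AA1 at 1.77 and CHORDC1 at 1.79. Of NRF2 targets, 8 rose, 0 fell and 7 did not pass (9 and 0 adjusted over the list alone, median 0.89, adjusted p = 9.0e-44, adjusted p = 0.0094 with an estimated correlation), with the thioredoxin reductase TXNRD1 at 1.72 and the glutathione enzyme GCLM at 2.17. Ribosome biogenesis genes fell: 0 rose, 26 fell and 4 did not pass (0 and 26 adjusted over the list alone, median -0.51, adjusted p = 1.1e-27, adjusted p = 0.018 with an estimated correlation). Of STAT5 targets, 0 rose, 11 fell and 5 did not pass (3 and 12 adjusted over the list alone, median -0.52, adjusted p = 3.5e-10, adjusted p = 0.041 with an estimated correlation). PIM2 was at -0.87, CCND2 at -0.76 and ID1 at -1.01. Of stem and progenitor genes, 0 rose, 6 fell and 7 did not pass (0 and 6 adjusted over the list alone, median -0.39, adjusted p = 1.7e-07, adjusted p = 0.033 with an estimated correlation). The transcription factor GATA2 was at -1.29 and MECOM at -0.61. Of ERK feedback genes, 1 rose, 8 fell and 19 did not pass (4 and 11 adjusted over the list alone, median -0.28, adjusted p = 6.6e-04, adjusted p = 0.069 with an estimated correlation). JUNB (-1.04) and LIF (-1.19) were among those that fell.

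For DNA replication genes, 0 rose, 10 fell and 27 did not pass (0 and 21 adjusted over the list alone, median -0.45, adjusted p = 3.5e-10, adjusted p = 0.60 with an estimated correlation). Cholesterol synthesis genes moved down, where 1 rose, 11 fell and 12 did not pass (1 and 17 adjusted over the list alone, median -0.39, adjusted p = 1.3e-07, adjusted p = 0.26 with an estimated correlation). DHCR7 was at -0.71 and MVK at -0.78. ATF4 response genes moved up, where 5 rose, 0 fell and 21 did not pass (7 and 0 adjusted over the list alone, median 0.23, adjusted p = 2.8e-06, adjusted p = 0.60 with an estimated correlation). SLC7A11 was at 2.09 and ATF3 at 0.86. Endoplasmic reticulum stress genes moved up as well, and 4 rose, 0 fell and 15 did not pass (5 and 0 adjusted over the list alone, median 0.11, adjusted p = 0.017, adjusted p = 0.66 with an estimated correlation). HERPUD1 was at 0.72 and DNAJB9 at 1.03. Lists that did not pass were the interferon-stimulated genes (2 up, 1 down, 3 and 2 adjusted over the list alone, median -0.02, mean 0.10, test direction up, adjusted p = 0.84), the NF-kappaB genes (1 up, 2 down, 2 and 4 adjusted over the list alone, median -0.14, adjusted p = 0.20), with ICAM1 at -1.44, and the S100 genes (0 passed, also adjusted over the list alone, median -0.07, adjusted p = 0.87). Mitosis (1 up, 0 down, 1 and 0 adjusted over the list alone, median 0.06, adjusted p = 0.61), lymphoid (0 passed, also adjusted over the list alone, median -0.17, adjusted p = 0.73) and epithelial genes (0 passed, also adjusted over the list alone, median -0.15, mean 0.02, test direction down, adjusted p = 0.87) did not pass either.

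Counts at 4 h used the edgeR quasi-likelihood test and lists the camera test. A fold change of at least 1.5 left 1178 genes, and a fit of only the 4 libraries compared called 5691. With 1 library left out the number was 648 without DMSO 1, 555 without DMSO 2, 574 without BCI 1 and 693 without BCI 2, and 5 of the 10 lists passed with an estimated correlation.

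The same was asked at 48 h. In the main fit edgeR called 0 genes, with 316 at unadjusted p under 0.05, where 5% would be 1095. DESeq2 called 0, with 238, and limma-voom 0, with 314. A replicate block called 0 with all groups and 18 with only those compared, with 1529. DUSP6, the ERK phosphatase, lay at 28.6 ± 0.552 CPM against 29.1 ± 2.60 (log2 -0.03, SE 0.0975, adjusted p = 1). DUSP1 (7.81 ± 0.207 against 8.81 ± 1.57; log2 -0.17, SE 0.162, adjusted p = 1), PIM1 (754 ± 108 against 757 ± 158; log2 -0.01, SE 0.136, adjusted p = 1) and MYC (1017 ± 188 against 963 ± 197; log2 0.08, SE 0.144, adjusted p = 1) did not pass. Nor did RPS6KA1 (0.04, adjusted p = 1), JAK2 (-0.01, adjusted p = 1), EGR1 (-0.29, adjusted p = 1) or CISH (-0.04, adjusted p = 1).

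Small shifts over whole lists at 48 h passed with the preset correlation only, and no member of any list passed alone. They ran up in mitosis (median 0.19, adjusted p = 2.3e-11, adjusted p = 0.90 with an estimated correlation) and DNA replication genes (median 0.16, adjusted p = 5.2e-10, adjusted p = 0.90 with an estimated correlation). ATF4 response genes (median 0.13, adjusted p = 6.7e-08, adjusted p = 0.90 with an estimated correlation) and endoplasmic reticulum stress genes (median 0.09, adjusted p = 0.017, adjusted p = 0.90 with an estimated correlation) were also up. So were ribosomal protein genes (median 0.05, adjusted p = 0.017, adjusted p = 0.94 with an estimated correlation) and ribosome biogenesis genes (median 0.05, adjusted p = 0.028, adjusted p = 0.90 with an estimated correlation). ERK feedback genes (median -0.03, adjusted p = 0.029, adjusted p = 0.90 with an estimated correlation) and replication-dependent histone genes (median -0.31, adjusted p = 0.020, adjusted p = 0.90 with an estimated correlation) were down. The STAT5 targets (0 passed, also adjusted over the list alone, median -0.01, mean 0.04, test direction down, adjusted p = 0.91), the S100 genes (0 passed, also adjusted over the list alone, median -0.07, adjusted p = 0.22), the interferon-stimulated genes (0 passed, also adjusted over the list alone, median 0.02, mean -0.03, test direction up, adjusted p = 0.96) and the NF-kappaB genes (0 passed, also adjusted over the list alone, median -0.002, adjusted p = 0.71) did not pass. Lymphoid (0 passed, also adjusted over the list alone, median -0.02, adjusted p = 0.96) and epithelial genes (0 passed, also adjusted over the list alone, median -0.07, adjusted p = 0.30) did not pass. Without the low-count filter 27 genes passed. The number of lists was 14 without DMSO 1, 4 without DMSO 2 and 2 without BCI 1, against 8 with all, and 7, 1 and 0 of these were among the 8.

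Whether the response differed between the times was tested as the difference of the log2 fold changes, later minus 4 h. It passed for 757 genes, 456 with a higher and 301 with a lower value at 48 h. The largest differences lay in the genes that rose most at 4 h. For HMOX1, the haem-degrading enzyme, the difference was -7.44 (SE 0.258, adjusted p = 3.6e-06), with 8.14 ± 2.02 against 10.7 ± 2.00 CPM (mean ± SD, n = 2) in BCI and DMSO at 48 h. The chaperones HSPA6 (-7.05 (SE 1.41, adjusted p = 0.029)) and DNAJB1 (-3.27 (SE 0.167, adjusted p = 3.0e-05)) and the stress gene OSGIN1 (-5.77 (SE 0.632, adjusted p = 0.0023)) differed in the same direction. HSPA1A (-5.29 (SE 0.633, adjusted p = 0.0033)) and HSPA1B (-4.91 (SE 0.437, adjusted p = 8.0e-04)) did too, with an uncertain split between these near-identical copies. In the other direction lay TRIM67 (2.77 (SE 0.290, adjusted p = 0.0018)), PRF1 (2.02 (SE 0.424, adjusted p = 0.034)), WNT11 (1.91 (SE 0.141, adjusted p = 2.3e-04)) and CCND1 (1.66 (SE 0.222, adjusted p = 0.0053)), a ubiquitin ligase, perforin, a secreted ligand and a cyclin.

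Of the genes followed, DUSP6 (0.98 (SE 0.139, adjusted p = 0.0072)), DUSP1 (-1.51 (SE 0.229, adjusted p = 0.0094)) and RPS6KA1 (0.68 (SE 0.110, adjusted p = 0.013)) had different responses at the 2 times. PIM1 (0.72, adjusted p = 0.083), CISH (0.43, adjusted p = 0.14), MYC (0.64, adjusted p = 0.13), JAK2 (-0.27, adjusted p = 0.32) and EGR1 (-0.85, adjusted p = 0.16) did not pass. DUSP6 and RPS6KA1 did not pass with any 1 library of 4 h left out (highest adjusted p = 0.072 and 0.12), nor did DUSP1 without 3 of these 4 (0.079). PIM1 (0.0048) and MYC (0.019) passed with DESeq2. PRF1 did not pass with GC and length trends removed (0.054). The heat shock list had the lowest value, where 0 rose, 16 fell and 2 did not pass (0 and 17 adjusted over the list alone, median -1.50, adjusted p = 2.6e-98, adjusted p = 0.0095 with an estimated correlation). NRF2 targets were lower, and 0 rose, 8 fell and 7 did not pass (0 and 8 adjusted over the list alone, median -1.06, adjusted p = 6.1e-42, adjusted p = 0.013 with an estimated correlation). Ribosome biogenesis genes were higher, and 20 rose, 0 fell and 10 did not pass (26 and 0 adjusted over the list alone, median 0.57, adjusted p = 7.0e-27, adjusted p = 0.020 with an estimated correlation). For STAT5 targets, 5 rose, 0 fell and 11 did not pass (11 and 0 adjusted over the list alone, median 0.54, adjusted p = 3.1e-08, adjusted p = 0.064 with an estimated correlation). In DNA replication, 4 rose, 0 fell and 33 did not pass (19 and 0 adjusted over the list alone, median 0.61, adjusted p = 2.2e-15, adjusted p = 0.51 with an estimated correlation).

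ERK feedback genes were higher in the same test, where 4 rose, 0 fell and 24 did not pass (9 and 4 adjusted over the list alone, median 0.21, mean -0.24, test direction up, adjusted p = 0.035, adjusted p = 0.23 with an estimated correlation), but did not pass with GC and length trends removed (adjusted p = 0.071). Interferon-stimulated (0 up, 1 down, 0 and 1 adjusted over the list alone, median -0.05, adjusted p = 0.86), NF-kappaB (2 up, 0 down, 2 and 1 adjusted over the list alone, median 0.09, adjusted p = 0.41) and S100 genes (0 passed, also adjusted over the list alone, median 0.03, mean -0.22, test direction down, adjusted p = 0.86) did not pass. Mitosis (0 passed, also adjusted over the list alone, median 0.12, adjusted p = 0.23), lymphoid (0 passed, also adjusted over the list alone, median 0.23, mean -0.09, test direction up, adjusted p = 0.82) and epithelial genes (0 passed, also adjusted over the list alone, median -0.03, adjusted p = 0.86) did not pass. The count was 1658 without the low-count filter and 1378 with DESeq2. It was 138 and 88 without DMSO 1 or 2 at 4 h, 110 and 129 without BCI 1 or 2 at 4 h, 1705 without DMSO 1 and 436 without BCI 1 at 48 h. Across genes the 2 responses had Pearson r -0.034. Genes are not independent replicates.

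The next question was what BI-D1870 does to HEL cells. BI-D1870 changed 10045 of 21328 genes, 4867 up and 5178 down, with 719 up and 1723 down at least 2-fold. The cytokine IL1B (ENSG00000125538) fell most (2.29 ± 0.0362 CPM against 93.1 ± 7.42, mean ± SD, n = 2; log2 -5.34, SE 0.0929, adjusted p = 1.3e-18). The vascular growth factor ANGPT1 (3.29 ± 0.292 against 76.4 ± 3.76; log2 -4.54, SE 0.0854, adjusted p = 3.3e-18) and the growth factor binder IGFBP5 (125 ± 2.00 against 1412 ± 13.5; log2 -3.50, SE 0.0420, adjusted p = 4.0e-21) fell too. Rises were smaller. SLFN5, an interferon-inducible Schlafen gene (8.73 ± 0.178 against 1.30 ± 0.332; log2 2.75, SE 0.158, adjusted p = 2.6e-11), the AP-1 subunit JUN (52.7 ± 1.13 against 8.28 ± 0.223; log2 2.67, SE 0.0727, adjusted p = 6.4e-16) and the histone gene H2BC12 (82.6 ± 4.26 against 15.9 ± 0.767; log2 2.38, SE 0.0620, adjusted p = 3.3e-16) led them.

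Under BI-D1870 PIM1 fell furthest of the genes followed (156 ± 4.64 CPM against 639 ± 44.3; log2 -2.04, SE 0.0464, adjusted p = 4.1e-17), and MYC fell (528 ± 13.3 against 920 ± 11.4; log2 -0.80, SE 0.0369, adjusted p = 1.2e-12). CISH fell by little (log2 -0.26, SE 0.0587, adjusted p = 9.6e-04) and did not pass without BI-D1870 2 (adjusted p = 0.073). EGR1 rose (36.6 ± 1.47 against 17.2 ± 0.246; log2 1.08, SE 0.0763, adjusted p = 5.5e-10), and so did RPS6KA1 (log2 0.45, SE 0.0393, adjusted p = 1.2e-08), DUSP6 (29.6 ± 1.85 against 22.3 ± 0.319; log2 0.41, SE 0.0674, adjusted p = 4.8e-05) and JAK2 (log2 0.22, SE 0.0421, adjusted p = 2.6e-04). DUSP1 did not pass (0.18, adjusted p = 0.22).

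Lineage genes fell under BI-D1870. In the megakaryocyte and platelet list 2 rose, 16 fell and 0 did not pass (2 and 16 adjusted over the list alone, median -0.81, adjusted p = 3.2e-13, adjusted p = 0.15 with an estimated correlation). SELP was at -2.68, PLEK at -1.54 and GP9 at -1.86. For erythroid genes, 1 rose, 21 fell and 5 did not pass (2 and 21 adjusted over the list alone, median -0.43, adjusted p = 1.4e-11, adjusted p = 0.15 with an estimated correlation). EPB42 was at -2.67. For monocyte and granulocyte genes, 3 rose, 9 fell and 5 did not pass (3 and 9 adjusted over the list alone, median -0.37, adjusted p = 0.0022, adjusted p = 0.16 with an estimated correlation). SPI1 was at -1.48 and VCAN at -2.69. Stem and progenitor genes were down as well: 2 rose, 7 fell and 4 did not pass (2 and 7 adjusted over the list alone, median -0.46, adjusted p = 1.2e-04, adjusted p = 0.15 with an estimated correlation). MYB was at -1.62 and LMO2 at -1.21. Of the lymphoid markers, 0 rose, 6 fell and 1 did not pass (0 and 6 adjusted over the list alone, median -1.79, adjusted p = 0.0082, adjusted p = 0.16 with an estimated correlation). CD2 was at -2.42. Of the epithelial and stromal markers, 1 rose, 4 fell and 1 did not pass (1 and 4 adjusted over the list alone, median -1.26, adjusted p = 0.042, adjusted p = 0.35 with an estimated correlation), and that list did not pass with halved counts (adjusted p = 0.059).

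Immune lists fell with BI-D1870 too. For NF-kappaB genes, 2 rose, 11 fell and 5 did not pass (2 and 12 adjusted over the list alone, median -0.57, adjusted p = 3.7e-04, adjusted p = 0.15 with an estimated correlation). TNFAIP3 was at -1.78 and SOD2 at 0.71. Interferon-stimulated genes were down, and 5 rose, 18 fell and 6 did not pass (5 and 18 adjusted over the list alone, median -0.70, adjusted p = 0.0082, adjusted p = 0.15 with an estimated correlation). IFITM1 was at -2.61 and IRF7 at 1.64. In antigen presentation, 1 rose, 16 fell and 2 did not pass (1 and 16 adjusted over the list alone, median -0.45, adjusted p = 1.2e-04, adjusted p = 0.21 with an estimated correlation). NLRC5 was at -1.07 and PSMB8 at -0.996. STAT5 targets were down, and 5 rose, 9 fell and 2 did not pass (5 and 9 adjusted over the list alone, median -0.27, adjusted p = 8.9e-04, adjusted p = 0.15 with an estimated correlation). CCND2 was at -1.46 and MCL1 at 0.76. DNA replication was down, where 4 rose, 24 fell and 9 did not pass (4 and 25 adjusted over the list alone, median -0.25, adjusted p = 6.0e-08, adjusted p = 0.15 with an estimated correlation). Hypoxia and glycolysis genes were down, where 3 rose, 19 fell and 5 did not pass (3 and 19 adjusted over the list alone, median -0.58, adjusted p = 6.3e-10, adjusted p = 0.18 with an estimated correlation).

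Lists that rose with BI-D1870 were the histone genes, where 11 rose, 2 fell and 3 did not pass (12 and 4 adjusted over the list alone, median 1.33, adjusted p = 6.0e-08, adjusted p = 0.15 with an estimated correlation) (H2AC6 2.27, H1-2 1.38), and the p53 targets, where 13 rose, 5 fell and 3 did not pass (13 and 5 adjusted over the list alone, median 0.17, adjusted p = 8.9e-04, adjusted p = 0.15 with an estimated correlation). BTG2 was at 1.72 and CDKN1A at 1.52. Mitochondrially encoded genes rose: 13 rose, 0 fell and 0 did not pass (13 and 0 adjusted over the list alone, median 0.72, adjusted p = 3.5e-16, adjusted p = 0.16 with an estimated correlation). MT-CYB was at 0.98. Mitochondrial transcripts held 6.17% and 6.198% of counts, against 3.58% and 3.64% in DMSO. ERK feedback genes split and did not pass as a list (11 up, 8 down, 11 and 8 adjusted over the list alone, median 0.19, adjusted p = 0.72), with ETV4 at -2.50 and LIF at -3.04. Mitosis genes (5 up, 17 down, 5 and 18 adjusted over the list alone, median -0.14, adjusted p = 0.096), with MKI67 at -0.78 and CDC20 at 0.49, and S100 genes (1 up, 5 down, 1 and 5 adjusted over the list alone, median -0.46, adjusted p = 0.21) did not pass either. A fold change of at least 1.5 left 4477 genes, and 0 of the 16 lists passed with an estimated correlation.

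BI-D1870 with BCI was compared with DMSO to ask what both inhibitors do together. The pair changed 9992 genes, 4818 up and 5174 down, with 801 up and 1543 down at least 2-fold. ANGPT1 (3.15 ± 0.0913 CPM against 76.4 ± 3.76, mean ± SD, n = 2; log2 -4.60, SE 0.0839, adjusted p = 2.3e-18), IL1B (4.38 ± 0.406 against 93.1 ± 7.42; log2 -4.41, SE 0.0828, adjusted p = 3.2e-18) and IGFBP5 (114 ± 4.43 against 1412 ± 13.5; log2 -3.63, SE 0.0422, adjusted p = 2.1e-21), all genes of secreted proteins, fell most. SLFN5 (8.84 ± 0.316 against 1.30 ± 0.332; log2 2.77, SE 0.156, adjusted p = 1.9e-11) and H2BC12 (95.2 ± 5.31 against 15.9 ± 0.767; log2 2.58, SE 0.0617, adjusted p = 7.2e-17) rose. PIM1 (163 ± 1.37 against 639 ± 44.3; log2 -1.97, SE 0.0461, adjusted p = 5.7e-17), MYC (469 ± 8.87 against 920 ± 11.4; log2 -0.97, SE 0.0370, adjusted p = 6.9e-14) and CISH (log2 -0.24, SE 0.0581, adjusted p = 0.0017) fell. EGR1 (48.5 ± 5.65 against 17.2 ± 0.246; log2 1.49, SE 0.0752, adjusted p = 4.1e-12), DUSP6 (33.9 ± 0.799 against 22.3 ± 0.319; log2 0.60, SE 0.0665, adjusted p = 2.8e-07) and RPS6KA1 (log2 0.55, SE 0.0392, adjusted p = 6.2e-10) rose. DUSP1 (0.21, adjusted p = 0.13) and JAK2 (0.01, adjusted p = 0.87) did not pass.

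With both inhibitors the erythroid list had the smallest p: 1 rose, 24 fell and 2 did not pass (1 and 24 adjusted over the list alone, median -0.70, adjusted p = 2.7e-27, adjusted p = 0.12 with an estimated correlation). EPB42 was at -2.79 and HBE1 at -2.14. Antigen presentation genes were down, and 0 rose, 16 fell and 3 did not pass (0 and 16 adjusted over the list alone, median -0.79, adjusted p = 3.2e-10, adjusted p = 0.12 with an estimated correlation). STAT5 targets were down, where 5 rose, 9 fell and 2 did not pass (6 and 9 adjusted over the list alone, median -0.32, adjusted p = 1.0e-04, adjusted p = 0.12 with an estimated correlation). CCND2 was at -1.86 and MCL1 at 0.80. NF-kappaB genes were down, where 2 rose, 12 fell and 4 did not pass (2 and 12 adjusted over the list alone, median -0.46, adjusted p = 7.5e-04, adjusted p = 0.12 with an estimated correlation). Interferon-stimulated genes were down, where 5 rose, 17 fell and 7 did not pass (5 and 18 adjusted over the list alone, median -0.73, adjusted p = 0.0096, adjusted p = 0.14 with an estimated correlation). Lymphoid markers were down, where 0 rose, 6 fell and 1 did not pass (0 and 6 adjusted over the list alone, median -1.24, adjusted p = 0.028, adjusted p = 0.21 with an estimated correlation).

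DNA replication genes fell with both inhibitors: 1 rose, 27 fell and 9 did not pass (1 and 27 adjusted over the list alone, median -0.31, adjusted p = 2.0e-10, adjusted p = 0.12 with an estimated correlation). Mitosis genes were down, and 4 rose, 19 fell and 7 did not pass (4 and 19 adjusted over the list alone, median -0.20, adjusted p = 0.019, adjusted p = 0.63 with an estimated correlation). MKI67 was at -0.70 and CDC20 at 0.44. In the heat shock list, 4 rose, 12 fell and 2 did not pass (4 and 12 adjusted over the list alone, median -0.51, adjusted p = 3.0e-06, adjusted p = 0.17 with an estimated correlation). Mitochondrially encoded genes were up, where 12 rose, 0 fell and 1 did not pass (12 and 0 adjusted over the list alone, median 0.33, adjusted p = 1.6e-05, adjusted p = 0.36 with an estimated correlation). MT-CYB was at 0.79. Their transcripts held 5.72% and 5.29% of counts, against the DMSO shares above. BCL2 family genes were up, where 7 rose, 1 fell and 6 did not pass (7 and 1 adjusted over the list alone, median 0.16, adjusted p = 0.038, adjusted p = 0.21 with an estimated correlation). BCL2L11 was at 0.60 and BCL2 at -0.93. ERK feedback (12 up, 7 down, 13 and 7 adjusted over the list alone, median 0.14, adjusted p = 0.61), S100 (0 up, 4 down, 0 and 4 adjusted over the list alone, median -0.33, adjusted p = 0.35) and epithelial genes (1 up, 2 down, 1 and 2 adjusted over the list alone, median -0.61, adjusted p = 0.28) did not pass.

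For the pair, a fold change of at least 1.5 left 4462 genes, and 0 of the 18 lists passed with an estimated correlation. Across genes the responses to BI-D1870 with and without BCI had Pearson r 0.857, against 0.515 in simulated tables with no change and the same shared control. Their covariance was 0.663 against 0.0595. Of called genes 4055 were up in both, 4378 down in both and 22 opposite, where independent calls would give 1099 and 1256. Part of the excess may come from the shared control, whose 2 libraries were not split.

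What BCI adds to BI-D1870 was tested between the 2 treated groups. It changed 1004 genes, 474 up and 530 down, and 20 and 24 of these at least 2-fold. NQO1, a quinone reductase (11.8 ± 0.107 CPM against 4.41 ± 0.621, mean ± SD, n = 2; log2 1.42, SE 0.125, adjusted p = 1.1e-06), GSTP1, a glutathione transferase (29.2 ± 0.349 against 12.98 ± 0.0168; log2 1.17, SE 0.0784, adjusted p = 1.9e-08), and FTL, the ferritin light chain (4092 ± 180 against 1890 ± 5.54; log2 1.11, SE 0.0362, adjusted p = 1.9e-13), rose most. The chaperone HSPA8 (1774 ± 26.5 against 3912 ± 52.6; log2 -1.14, SE 0.0338, adjusted p = 7.0e-14), the helicase subunit MCM7 (134 ± 2.41 against 227 ± 2.31; log2 -0.76, SE 0.0391, adjusted p = 3.2e-10), HMOX1 (4.22 ± 0.504 against 9.20 ± 0.791; log2 -1.12, SE 0.128, adjusted p = 2.5e-05) and JUN (27.4 ± 1.58 against 52.7 ± 1.13; log2 -0.95, SE 0.0638, adjusted p = 1.9e-08) fell. Falls of the alpha globins HBA1 (-1.29 (SE 0.0462, adjusted p = 7.8e-13)) and HBA2 (-1.18 (SE 0.0487, adjusted p = 7.6e-12)) are uncertain in their split, as the genes are near-identical copies. The chaperonin HSPE1 fell (-0.87 (SE 0.0822, adjusted p = 2.2e-06)), as did the sum over it and its copies (-0.63). EGR1 rose (48.5 ± 5.65 against 36.6 ± 1.47; log2 0.41, SE 0.0709, adjusted p = 0.0016). JAK2 (log2 -0.21, SE 0.0420, adjusted p = 0.0061) and MYC (log2 -0.17, SE 0.0368, adjusted p = 0.0091) fell by little. Leaving out 1 library ended the calls of EGR1, JAK2 and MYC in some cases (highest adjusted p = 0.082, 0.12 and 0.16). DUSP6 (0.20, adjusted p = 0.10), DUSP1 (0.04, adjusted p = 0.92), RPS6KA1 (0.10, adjusted p = 0.18), PIM1 (0.07, adjusted p = 0.53) and CISH (0.02, adjusted p = 0.93) did not pass.

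Chaperones fell as a group when BCI was added. In the heat shock list 0 rose, 13 fell and 5 did not pass (0 and 15 adjusted over the list alone, median -0.25, adjusted p = 4.2e-54, adjusted p = 0.082 with an estimated correlation). HSP90AA1 was at -0.69 and DNAJA1 at -0.44. Of the erythroid genes, 0 rose, 16 fell and 11 did not pass (0 and 17 adjusted over the list alone, median -0.21, adjusted p = 1.8e-46, adjusted p = 0.10 with an estimated correlation). HBE1 was at -0.82. Of antigen presentation genes, 0 rose, 9 fell and 10 did not pass (1 and 9 adjusted over the list alone, median -0.23, adjusted p = 3.3e-16, adjusted p = 0.17 with an estimated correlation). HLA-B was at -0.75 and B2M at -0.31. For mitochondrially encoded genes, 0 rose, 13 fell and 0 did not pass (0 and 13 adjusted over the list alone, median -0.35, adjusted p = 1.3e-36, adjusted p = 0.17 with an estimated correlation). MT-ND4 was at -0.41. DNA replication was down, and 0 rose, 2 fell and 35 did not pass (0 and 2 adjusted over the list alone, median -0.07, adjusted p = 6.8e-04, adjusted p = 0.27 with an estimated correlation). Mitosis was down, and 0 rose, 3 fell and 27 did not pass (0 and 3 adjusted over the list alone, median -0.04, adjusted p = 0.027, adjusted p = 0.69 with an estimated correlation). PTTG1 was at -0.25. With GC and length trends removed the mitosis (adjusted p = 0.30) and NRF2 lists (0.076) did not pass.

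Up with BCI on top of BI-D1870 were the epithelial genes, where 2 rose, 0 fell and 4 did not pass (2 and 0 adjusted over the list alone, median 0.51, adjusted p = 0.0010, adjusted p = 0.27 with an estimated correlation). KRT18 was at 0.42 and CDH5 at 0.60. Monocyte and granulocyte genes were up, where 2 rose, 0 fell and 15 did not pass (3 and 1 adjusted over the list alone, median 0.16, adjusted p = 0.010, adjusted p = 0.27 with an estimated correlation). SPI1 was at 0.44 and CD33 at 0.23. NRF2 targets were up as a list but split, as 3 rose, 4 fell and 8 did not pass (4 and 6 adjusted over the list alone, median 0.03, adjusted p = 0.022, adjusted p = 0.38 with an estimated correlation). GCLM was at -0.36. ERK feedback (2 up, 2 down, 5 and 3 adjusted over the list alone, median 0.09, adjusted p = 0.86), STAT5 (1 up, 3 down, 1 and 3 adjusted over the list alone, median 0.01, mean -0.09, test direction down, adjusted p = 0.073), S100 (1 up, 1 down, 1 and 1 adjusted over the list alone, median 0.12, adjusted p = 0.34) and interferon-stimulated genes (1 up, 0 down, 1 and 0 adjusted over the list alone, median -0.005, mean 0.01, test direction up, adjusted p = 0.90) did not pass. NF-kappaB (2 up, 1 down, 3 and 1 adjusted over the list alone, median -0.03, mean 0.05, test direction up, adjusted p = 0.38) and lymphoid genes (0 passed, also adjusted over the list alone, median 0.33, adjusted p = 0.19) did not pass. A fold change of at least 1.5 left 115 genes. Leaving out BI-D1870 1 gave 367 genes and 6 of the 12 lists, BI-D1870 2 325 genes, the pair's library 1 565 and its library 2 393. With GC content the log2 fold change had Pearson r 0.29 across genes.

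Whether BCI genes respond to BI-D1870 was asked with the sets called at 4 h. Genes that fell with BCI at 4 h were lower under BI-D1870 (279 up and 690 down of 1297 tested, median log2 fold change -0.19, adjusted p = 2.7e-08, adjusted p = 0.061 with an estimated correlation) and under the pair (268 up and 668 down of 1297 tested, median log2 fold change -0.18, adjusted p = 1.3e-07, adjusted p = 0.061 with an estimated correlation). Those that rose with BCI were down when BCI was added to BI-D1870 (22 up and 65 down of 1039 tested, median log2 fold change -0.02, adjusted p = 0.020, adjusted p = 0.26 with an estimated correlation). The set that rose did not pass under BI-D1870 (adjusted p = 0.088) or the pair (adjusted p = 0.28), nor did the set that fell when BCI was added (adjusted p = 0.28). Pearson r between the responses to BCI at 4 h and BI-D1870 was 0.113 across genes, which are not independent replicates.

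The next question was what differs after long culture with ruxolitinib. RuxP cells had 681 genes higher and 345 lower than parental cells, of 15924 tested. The ETS factor FEV (22.01 ± 6.68 CPM against 0.178 ± 0.142, mean ± SD, n = 2; log2 6.91, SE 0.495, adjusted p = 0.0037), the surface protein CD24 (38.5 ± 0.329 against 0.385 ± 0.00341; log2 6.64, SE 0.204, adjusted p = 5.6e-04) and the ETS factor ETV4 (10.4 ± 3.94 against 0.134 ± 0.0805; log2 6.22, SE 0.477, adjusted p = 0.0041) were among the 10 largest rises. The deacetylase HDAC9 (0.223 ± 0.0255 against 9.39 ± 0.664; log2 -5.39, SE 0.421, adjusted p = 0.0041) and the platelet chemokine PF4 (1.68 ± 0.149 against 44.3 ± 13.9; log2 -4.72, SE 0.295, adjusted p = 0.0030) fell. None of the genes followed passed. DUSP6 lay at 3.73 ± 1.41 against 1.69 ± 1.45 (log2 1.15, SE 0.622, adjusted p = 0.31) and DUSP1 at 2.33 ± 0.846 against 5.71 ± 2.55 (log2 -1.29, SE 0.404, adjusted p = 0.12). RPS6KA1 (-0.17, adjusted p = 0.70), JAK2 (-0.34, adjusted p = 0.49), EGR1 (-0.07, adjusted p = 0.91), PIM1 (0.50, adjusted p = 0.25), CISH (0.63, adjusted p = 0.36) and MYC (-0.54, adjusted p = 0.32) did not pass. DUSP6 passed without parental 2 (2.49, adjusted p = 0.021) and DUSP1 with DESeq2 (adjusted p = 0.030). With GC and length trends removed DUSP1 (0.033), JAK2 (0.029), PIM1 (0.0013) and CISH (0.012) passed.

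Cell cycle lists were the most raised in RuxP cells. For mitosis genes, 25 rose, 0 fell and 5 did not pass (29 and 0 adjusted over the list alone, median 1.95, adjusted p = 1.1e-45, adjusted p = 0.069 with an estimated correlation). MKI67 was at 2.38, KIF11 at 2.15 and KIF2C at 2.01. For DNA replication, 27 rose, 0 fell and 10 did not pass (33 and 0 adjusted over the list alone, median 1.43, adjusted p = 1.2e-38, adjusted p = 0.018 with an estimated correlation). CDC45 was at 2.07 and MCM4 at 1.93. ERK feedback genes were up, and 7 rose, 0 fell and 18 did not pass (7 and 0 adjusted over the list alone, median 0.84, adjusted p = 1.2e-06, adjusted p = 0.11 with an estimated correlation). ETV5 was at 2.23, LIF at 3.34 and CCND1 at 2.71. Of STAT5 targets, 2 rose, 0 fell and 14 did not pass (6 and 1 adjusted over the list alone, median 0.48, adjusted p = 0.049, adjusted p = 0.68 with an estimated correlation), and the list did not pass with halved counts (adjusted p = 0.060). Of interferon-stimulated genes, 4 rose, 0 fell and 25 did not pass (9 and 2 adjusted over the list alone, median 0.42, adjusted p = 0.019, adjusted p = 0.32 with an estimated correlation). OAS3 was at 1.35.

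Platelet genes fell in RuxP cells: 0 rose, 14 fell and 6 did not pass (0 and 18 adjusted over the list alone, median -1.19, adjusted p = 1.2e-23, adjusted p = 0.11 with an estimated correlation). ITGB3 was at -2.62 and THBS1 at -3.64. Of the erythroid genes, 1 rose, 6 fell and 20 did not pass (2 and 12 adjusted over the list alone, median -0.51, adjusted p = 5.7e-04, adjusted p = 0.54 with an estimated correlation). HBE1 was at -3.30 and EPB42 at -1.25. NF-kappaB (0 up, 3 down, 0 and 3 adjusted over the list alone, median -0.37, adjusted p = 0.091) and S100 genes (0 passed, also adjusted over the list alone, median -0.07, mean 0.25, test direction up, adjusted p = 0.98) did not pass. Lymphoid (0 up, 0 down, 1 and 1 adjusted over the list alone, median 0.28, mean 0.89, test direction down, adjusted p = 0.98) and epithelial genes (1 up, 1 down, 1 and 1 adjusted over the list alone, median 0.74, adjusted p = 0.98), with CDH5 at -2.42, did not pass.

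Libraries of the persistent table differed in quality. Parental 2 and RuxP 1 had 3258 and 1712 genes with 1 to 10 counts, against 4644 to 5079 in the others. Mitochondrial transcripts held 15.6% and 23.6% of counts in parental, 25.8% and 23.1% in RuxP and 12.4% and 12.7% in FedP libraries. Log2 fold changes of RuxP against parental had Pearson r -0.30 with GC content across genes. The count of 1026 became 1836 without the low-count filter, 2407 (1225 higher and 1182 lower) with DESeq2, 419 in a fit of only these groups and 3408 (1843 higher and 1565 lower) with GC and length trends removed. It was 1550 without parental 1, 4157 without parental 2, 170 without RuxP 1, 517 without RuxP 2 and 9777 without parental 2 and RuxP 1 together.

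The same was asked of cells kept with fedratinib. FedP cells had 611 genes higher and 444 lower than parental cells. FEV (39.6 ± 1.24 CPM against 0.178 ± 0.142, mean ± SD, n = 2; log2 7.75, SE 0.505, adjusted p = 0.0033) and ETV4 (14.2 ± 1.16 against 0.134 ± 0.0805; log2 6.68, SE 0.480, adjusted p = 0.0035) rose here too, with the lipoxygenase ALOX5 (15.4 ± 0.544 against 0.349 ± 0.0266; log2 5.46, SE 0.240, adjusted p = 0.0019). The transcription cofactor EYA4 (0.154 ± 0.0479 against 15.4 ± 1.55; log2 -6.62, SE 0.371, adjusted p = 0.0019) and PF4 (1.65 ± 0.168 against 44.3 ± 13.9; log2 -4.74, SE 0.293, adjusted p = 0.0027) fell. PIM1, the STAT5 target, was the 1 gene followed that passed (858 ± 27.1 against 395 ± 120; log2 1.12, SE 0.234, adjusted p = 0.045). DUSP6 (8.17 ± 0.478 against 1.69 ± 1.45; log2 2.28, SE 0.631, adjusted p = 0.090) and EGR1 (4.65 ± 0.104 against 1.85 ± 0.556; log2 1.32, SE 0.301, adjusted p = 0.057) did not. DUSP1 (-0.66, adjusted p = 0.35), RPS6KA1 (0.43, adjusted p = 0.33), JAK2 (-0.81, adjusted p = 0.15), CISH (1.06, adjusted p = 0.15) and MYC (0.41, adjusted p = 0.43) did not pass. DUSP6 passed with DESeq2 (adjusted p = 0.0020), with GC and length trends removed (0.026) and without parental 1 (0.026) or 2 (0.018). With DESeq2 JAK2 (0.036), EGR1 (0.012) and CISH (0.028) passed. PIM1 did not pass without FedP 1 (0.22) or 2 (0.19).

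ERK feedback genes were raised in FedP cells: 8 rose, 0 fell and 17 did not pass (15 and 0 adjusted over the list alone, median 1.11, adjusted p = 1.0e-13, adjusted p = 0.11 with an estimated correlation). ETV5 was at 2.96 and CCND1 at 3.56. MAP kinase phosphatases were up, where 1 rose, 0 fell and 9 did not pass (4 and 0 adjusted over the list alone, median 0.51, adjusted p = 0.043, adjusted p = 0.59 with an estimated correlation). DUSP4 was at 2.14. STAT5 targets were up, where 6 rose, 0 fell and 10 did not pass (8 and 0 adjusted over the list alone, median 0.94, adjusted p = 4.7e-06, adjusted p = 0.59 with an estimated correlation). ID1 was at 2.01 and SOCS1 at 2.58. Antigen presentation was up, and 6 rose, 0 fell and 13 did not pass (12 and 0 adjusted over the list alone, median 0.78, adjusted p = 4.7e-06, adjusted p = 0.59 with an estimated correlation). CD74 was at 1.55. Interferon-stimulated genes were up, and 5 rose, 0 fell and 24 did not pass (11 and 0 adjusted over the list alone, median 0.41, adjusted p = 0.0049, adjusted p = 0.26 with an estimated correlation). IFITM1 was at 2.63. Cholesterol synthesis was up, and 4 rose, 0 fell and 20 did not pass (12 and 1 adjusted over the list alone, median 0.59, adjusted p = 3.2e-05, adjusted p = 0.16 with an estimated correlation). FDFT1 was at 1.15. MAP kinase phosphatases did not pass with GC and length trends removed (adjusted p = 0.30).

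Platelet genes fell in FedP cells: 0 rose, 12 fell and 8 did not pass (0 and 15 adjusted over the list alone, median -1.40, adjusted p = 3.8e-22, adjusted p = 0.16 with an estimated correlation). THBS1 was at -4.67 and GP1BA at -2.39. Mitochondrially encoded genes, whose share is given above, were down, where 0 rose, 2 fell and 11 did not pass (0 and 12 adjusted over the list alone, median -0.89, adjusted p = 1.5e-05, adjusted p = 0.59 with an estimated correlation). MT-CO2 was at -0.69. DNA replication (2 up, 2 down, 2 and 2 adjusted over the list alone, median 0.12, adjusted p = 0.59) and mitosis genes (2 up, 1 down, 2 and 1 adjusted over the list alone, median -0.05, mean 0.06, test direction up, adjusted p = 0.82) did not pass, with CCNE1 at 1.51 and BUB1 at -1.39. NF-kappaB (0 up, 2 down, 2 and 5 adjusted over the list alone, median -0.22, adjusted p = 0.27), S100 (1 up, 0 down, 1 and 0 adjusted over the list alone, median 0.15, adjusted p = 0.45), lymphoid (0 up, 0 down, 2 and 0 adjusted over the list alone, median 0.37, adjusted p = 0.44) and epithelial genes (2 up, 1 down, 3 and 1 adjusted over the list alone, median 1.16, adjusted p = 0.34) did not pass.

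Log2 fold changes of FedP against parental had Pearson r 0.34 with GC content across genes. The count of 1055 became 1818 without the low-count filter, 2495 (1257 higher and 1238 lower) with DESeq2, 568 in a fit of only these groups and 3699 (1744 higher and 1955 lower) with GC and length trends removed. It moved widely with 1 library left out, which leaves a lone library in a group, and the range is given below. Without parental 2 and RuxP 1 together only the FedP pair gave the spread, so that count is not given. Across genes the RuxP and FedP differences from parental had Pearson r 0.554, against 0.502 in simulated tables with no change and the same shared control. Their covariance was 0.659 against 0.193, and signs were the same in 57.8% against 66.7% of genes. Called genes included 296 up in both, 206 down in both and 1 opposite, where independent calls would give 26.1 and 9.62. Part of the excess may come from the shared parental libraries, also not split.

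FedP and RuxP cells, which differ in both inhibitor and culture, were compared. FedP cells had 37 genes higher and 185 lower than RuxP cells, and 1941 higher and 1683 lower with DESeq2, 2891 higher and 2892 lower in a fit of only these groups and 909 higher and 1380 lower with GC and length trends removed. The pyruvate kinase PKLR (17.2 ± 0.567 CPM against 2.78 ± 0.788, mean ± SD, n = 2; log2 2.63, SE 0.353, adjusted p = 0.034), the phosphatase PTPRF (85.7 ± 1.06 against 16.6 ± 4.79; log2 2.37, SE 0.362, adjusted p = 0.044) and the haem synthesis enzyme ALAS2 (97.1 ± 5.19 against 23.5 ± 5.93; log2 2.05, SE 0.301, adjusted p = 0.041) were higher. The replication protease FAM111B (0.985 ± 0.132 against 9.45 ± 3.71; log2 -3.26, SE 0.401, adjusted p = 0.027), CD24 (5.26 ± 0.00345 against 38.5 ± 0.329; log2 -2.87, SE 0.162, adjusted p = 0.018), the cohesin acetyltransferase ESCO2 (1.91 ± 0.0376 against 14.03 ± 2.38; log2 -2.87, SE 0.290, adjusted p = 0.019) and the checkpoint gene CLSPN (17.1 ± 0.350 against 125 ± 30.6; log2 -2.87, SE 0.421, adjusted p = 0.041) were lower. None of the genes followed passed: DUSP6 (1.13, adjusted p = 0.24), DUSP1 (0.63, adjusted p = 0.31), RPS6KA1 (0.60, adjusted p = 0.15), JAK2 (-0.46, adjusted p = 0.28), EGR1 (1.39, adjusted p = 0.082), PIM1 (0.61, adjusted p = 0.14), CISH (0.43, adjusted p = 0.44) and MYC (0.95, adjusted p = 0.11). EGR1 (0.0068) and MYC (0.014) passed with DESeq2.

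Cell cycle lists were lower in FedP than in RuxP cells. For mitosis, 0 rose, 22 fell and 8 did not pass (0 and 30 adjusted over the list alone, median -1.81, adjusted p = 1.6e-47, adjusted p = 0.074 with an estimated correlation). KIF11 was at -2.33 and CCNB1 at -1.60. For DNA replication, 0 rose, 22 fell and 15 did not pass (0 and 30 adjusted over the list alone, median -1.27, adjusted p = 9.6e-38, adjusted p = 0.018 with an estimated correlation). MCM10 was at -2.03 and CDC45 at -2.32. Mitochondrially encoded genes were lower, where 0 rose, 1 fell and 12 did not pass (0 and 13 adjusted over the list alone, median -1.20, adjusted p = 1.7e-09, adjusted p = 0.54 with an estimated correlation) (MT-CO2 -0.90), as were heat shock genes, where 0 rose, 1 fell and 17 did not pass (1 and 9 adjusted over the list alone, median -0.46, adjusted p = 0.0058, adjusted p = 0.30 with an estimated correlation). HSPA8 was at -1.16. STAT5 targets were higher, where 0 rose, 0 fell and 16 did not pass (0 and 0 adjusted over the list alone, median 0.63, adjusted p = 0.0097, adjusted p = 0.56 with an estimated correlation). ERK feedback was higher, where 0 rose, 0 fell and 25 did not pass (3 and 0 adjusted over the list alone, median 0.54, adjusted p = 0.017, adjusted p = 0.50 with an estimated correlation). With GC and length trends removed the STAT5 (adjusted p = 0.31) and ERK lists (0.094) did not pass.

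Between FedP and RuxP cells the interferon-stimulated (0 passed, also adjusted over the list alone, median -0.06, mean 0.20, test direction up, adjusted p = 0.68), NF-kappaB (0 passed, also adjusted over the list alone, median -0.02, mean 0.08, test direction up, adjusted p = 0.73), S100 (0 passed, also adjusted over the list alone, median 0.39, adjusted p = 0.43), lymphoid (0 up, 0 down, 3 and 0 adjusted over the list alone, median 0.33, adjusted p = 0.32) and epithelial genes (0 up, 0 down, 1 and 0 adjusted over the list alone, median 0.61, adjusted p = 0.27) did not pass. The log2 fold change had Pearson r 0.68 with GC content across genes. The count of 222 was 0 without RuxP 1, 0 without RuxP 2, 0 without FedP 1 and 0 without FedP 2. It was 2886 without the low-count filter and 445 with limma-voom.

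Whether the genes of persistent cells respond to BCI was asked with the 4 sets called against parental. At 4 h of BCI the set higher in RuxP was down (30 up and 93 down of 680 tested, median log2 fold change -0.13, adjusted p = 2.1e-04, adjusted p = 0.84 with an estimated correlation). The set higher in FedP was down (24 up and 103 down of 609 tested, median log2 fold change -0.11, adjusted p = 5.1e-05, adjusted p = 0.84 with an estimated correlation) and the set lower in FedP was up (68 up and 22 down of 437 tested, median log2 fold change 0.12, adjusted p = 0.0042, adjusted p = 0.84 with an estimated correlation). At 48 h the set higher in RuxP was up (0 up and 0 down of 680 tested, median log2 fold change 0.09, adjusted p = 1.1e-06, adjusted p = 0.84 with an estimated correlation). The set lower in RuxP did not pass at 4 h (adjusted p = 0.66) or 48 h (adjusted p = 0.16), nor did the FedP sets at 48 h (adjusted p = 0.66 and 0.70). Pearson r across genes with BCI at 4 h was -0.081 for RuxP and -0.144 for FedP. Of 8 tests 4 passed with all libraries and 7 without DMSO 1, DMSO 2 or BCI 2 at 48 h.

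Further lists did not pass at 4 h of BCI, namely the RSK and MSK kinases (0 up, 1 down, 0 and 2 adjusted over the list alone, median -0.32, adjusted p = 0.096), the JAK, STAT and cytokine receptor genes (1 up, 3 down, 2 and 3 adjusted over the list alone, median -0.14, adjusted p = 0.20) and the MAP kinase phosphatases (2 up, 4 down, 2 and 4 adjusted over the list alone, median -0.08, mean 0.01, test direction down, adjusted p = 0.48).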

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

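Tests of causes here were chosen after the data were seen, all but the removal of GC and length trends after the result they weigh. Others were planned. The genes and lists of the next 2 paragraphs are given because a test of the difference itself passed, between the BCI responses at 48 h and 4 h or between FedP and RuxP cells, and 3 patterns are weighed after them.

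Between the 2 times of BCI the response differed in 757 genes, as differences of log2 fold changes, 48 h minus 4 h. Positive ones were DUSP6 at 0.98, RPS6KA1 at 0.68, TRIM67 at 2.77, PRF1 at 2.02, WNT11 at 1.91, EPHA1 at 1.79 and CCND1 at 1.66. Negative ones were DUSP1 at -1.51, HMOX1 at -7.44, HSPA6 at -7.05, OSGIN1 at -5.77, HSPA1A at -5.29 and HSPA1B at -4.91. By median, lists with a passing difference were ERK feedback genes at 0.21, STAT5 target genes at 0.54, stem and progenitor genes at 0.37, DNA replication genes at 0.61, ribosome biogenesis genes at 0.57 and cholesterol synthesis genes at 0.41, and, below 0, ATF4 response genes at -0.0792, heat shock genes at -1.50, NRF2 target genes at -1.06 and drug efflux genes at -0.28. With an estimated correlation 3 of these 10 lists passed, the ribosome biogenesis, heat shock and NRF2 lists, and the others had adjusted p from 0.055 to 0.92. The ERK list did not pass with GC and length trends removed.

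Between FedP and RuxP cells 222 genes differed. Higher in FedP by log2 were PKLR at 2.63, PTPRF at 2.37, SHISA7 at 2.24, ALAS2 at 2.05 and FN3K at 1.99, and lower were FAM111B at -3.26, CD24 at -2.87, ESCO2 at -2.87, CLSPN at -2.87 and DIAPH3 at -2.82. By median, higher lists were ERK feedback genes at 0.54, MAP kinase phosphatases at 0.97, STAT5 target genes at 0.63, antigen presentation genes at 0.61, erythroid genes at 0.86, ribosomal protein genes at 0.51, cholesterol synthesis genes at 0.38 and histone genes at 0.81, and lower lists DNA replication genes at -1.27, mitosis genes at -1.81, heat shock genes at -0.46 and mitochondrially encoded genes at -1.20. With an estimated correlation 1 of these 12 passed, the DNA replication list, and the others had adjusted p from 0.074 to 0.64. With GC and length trends removed 8 of them passed, and the ERK, MAP kinase phosphatase, STAT5 and antigen presentation lists did not.

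Mitosis and DNA replication genes were higher in RuxP than in parental cells, with a mitosis median of log2 1.95 (adjusted p = 0.069 for mitosis and 0.018 for DNA replication with an estimated correlation). Without the 2 libraries of low complexity that median was 2.08, between lone libraries, too few to weigh this cause. With the trends of the libraries with GC content and transcript length removed it was 1.83, which speaks against those trends as the whole cause. Persistence under ruxolitinib and a different growth state at harvest both stay open, since the design holds no measure of growth.

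The heat shock and NRF2 response to BCI at 4 h was absent at the later time. For 16 of the 17 heat shock genes that rose at 4 h, the 95% interval in a fit of the later libraries alone lay below 0.5 of the 4 h rise, which speaks against too little precision as the cause. The largest difference in heat shock list level between the 2 libraries of a later group was log2 0.104, which speaks against libraries swapped between BCI and DMSO. With 0 genes past the threshold, a response that faded cannot be told apart from later BCI libraries that were in effect untreated, because the genes called under some alternatives (27 without the low-count filter) are not known to mark the treatment. The column headings give 24 h for these libraries and the labels 48 h, so the time itself is open too.

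Heat shock genes were lower and NQO1, GSTP1 and FTL higher when BCI was added to BI-D1870, though the heat shock list did not pass with an estimated correlation (adjusted p = 0.082). For genes other than HSPE1 the sum over near-identical copies kept at least 98.7% of the log2 change, which speaks against reads moved between copies. For HSPE1 that sum changed by log2 -0.63 (95% interval -1.02 to -0.23), which speaks against reads moved between copies as the whole cause. The heat shock median was log2 -0.25, and an effect of BCI at 24 h that does not need BI-D1870 cannot be told apart from one that does, because the labels give no group with BCI alone at 24 h. If the headings of the BCI table are right, its later libraries are such a group, with a heat shock median of 0.01.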

How the results depend on the processing

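Each group held 2 libraries, so a library left out leaves a lone one that is assumed to vary like the other groups. All alternatives were chosen before the data were examined, except halved counts, removed trends, the 2 libraries left out together and the block with only 2 groups, which were added after. The cause of a changed count was not tested unless stated. Depth of at least 51799814 counts limits rare transcripts, and the spread between libraries was largest in the persistent table (biological coefficient of variation 26.9%). Every count of genes was within 1.5 times its value with DESeq2 size factors, the stricter filter and halved counts.

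With an estimated correlation the numbers of lists went from 10 to 5 for BCI at 4 h, 8 to 0 at 48 h, 10 to 3 between the times, 16 to 0 for BI-D1870, 18 to 0 for the pair, 12 to 0 for BCI on top, 13 to 1 for RuxP, 10 to 0 for FedP and 12 to 1 for FedP against RuxP. Persistent-cell sets under BCI went from 4 to 0, and BCI sets under BI-D1870 from 3 to 0. Sets of at least 2-fold changed genes kept both counts within 1.5 times.

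A fold change of at least 1.5 left 1178 genes for BCI at 4 h, 4477 for BI-D1870, 4462 for the pair and 115 for BCI on top, fewer by construction. Without the low-count filter 27 genes passed for BCI at 48 h, 1658 between the times, 1836 in RuxP, 1818 in FedP and 2886 between these. A fit of only the groups compared gave 5691 for BCI at 4 h, 419 for RuxP, 568 for FedP and 5783 between them. DESeq2 gave 1378 between the times, 2407 for RuxP, 2495 for FedP and 3624 between them, where limma-voom gave 445. With GC and length trends removed RuxP had 3408, FedP 3699 and their difference 2289. Without the 2 least complex libraries the numbers were 9777, 9120 and 9913. Among genes with a mean of at least 4 CPM, Pearson r went from 0.857 to 0.963 for BI-D1870 and the pair, and from 0.554 to 0.458 for RuxP and FedP.

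With 1 library left out, called genes ranged over 555 to 693 for BCI at 4 h, 88 to 1705 between the times, 325 to 565 for BCI on top, 170 to 4157 for RuxP, 197 to 5293 for FedP and 0 to 0 between them, against 2354, 757, 1004, 1026, 1055 and 222. Lists ranged over 2 to 14 for BCI at 48 h, 0 to 7 of them among the 8, and 6 to 13 for BCI on top, and persistent-cell sets over 4 to 7. Without RuxP 2 the median of all genes was -0.13 for RuxP and 0.14 for FedP against RuxP, against -0.04 and 0.04.

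Named-gene values never turned direction past the threshold. With a library left out 1942 stayed on their side, 456 lost and 18 gained the call. These numbers were 543, 5 and 9 with DESeq2, 534, 15 and 8 with trends removed, 553, 4 and 0 with DESeq2 size factors, and 555, 1 and 0 with halved counts.

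Replicate numbers are not known to pair samples. Deviations of equally numbered libraries had correlations of 0.316 for DMSO and BCI at 48 h, 0.119 for DMSO and the pair, and -0.222 for parental and RuxP. A replicate block gave 1166 genes between the times, 324 for RuxP, 272 for FedP and 0 between them, and 18 for BCI at 48 h with 2 groups. Of named-gene values under the block, 71 lost and 2 gained the call, and no other count moved by over 1.5 times.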

Other observations

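DMSO libraries of the 2 times differed by themselves, which belongs to no comparison of the report. This test was chosen after the data were seen, as were the genes named. Of 21908 genes, 2950 were higher and 2887 lower in DMSO at 48 h than at 4 h. Among endoplasmic reticulum stress genes 1 rose, 16 fell and 2 did not pass, with median log2 -1.40, adjusted p = 4.4e-50, adjusted p = 0.059 with an estimated correlation. The chaperone HSPA5 fell from 1171 ± 0.280 to 222 ± 22.1 CPM (log2 -2.40, SE 0.117, adjusted p = 2.8e-05), and others were SDF2L1 at log2 -2.94 and HSP90B1 at log2 -1.69. Among cholesterol synthesis genes 1 rose, 21 fell and 2 did not pass, with median log2 -0.99, adjusted p = 2.2e-26, adjusted p = 0.059 with an estimated correlation (HMGCS1 at log2 -2.07, DHCR7 at log2 -1.62). Among ribosome biogenesis genes 0 rose, 27 fell and 3 did not pass, with median log2 -0.56, adjusted p = 9.9e-23, adjusted p = 0.059 with an estimated correlation (PES1 at log2 -1.14, UTP20 at log2 -1.13). Among heat shock genes 0 rose, 13 fell and 5 did not pass, with median log2 -0.80, adjusted p = 2.5e-14, adjusted p = 0.090 with an estimated correlation (HSPH1 at log2 -1.31).

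Time in culture and any difference in handling between the times were not separated by the design.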
